A study of Rattus norvegicus with 6 samples.

How the data were processed

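Polyadenylated RNA from the rat trophoblast line Rcho-1 was sequenced after 8 days of differentiation in 6 libraries, 3 from cells transduced with a control shRNA and 3 from cells transduced with an shRNA against Cited2. The libraries were made from 500 ng of RNA each with a TruSeq RNA kit, per the labels' protocols. The groups and the replicate numbers were taken from the sample titles and treatment labels.

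Each library came as 1 table of 28068 annotated transcripts of 24385 genes. The tables hold whole-number counts of total and unique reads per transcript, per the file headers. They also hold RPKM values, per the file headers, and the column of expression values equals RPKM in every row. A ratio column in the deposited tables was not used. The genome build was Rnor 5.0, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here, nor is whether counting used strand. The authors' RPKM values had a denominator of 18608474 to 27116261 reads per library, and transcript reads made up 66.0 to 68.0% of it. That denominator therefore counts reads outside the annotated transcripts too.

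Total transcript reads were summed per gene, which gave 12599613, 18083789 and 17424693 reads in control libraries 1 to 3 and 17361387, 15123441 and 17926813 in Cited2 shRNA libraries 1 to 3. Genes with at least 1 read numbered 14950 to 15567 per library. A count of 0 allows up to 3 reads, or 0.166 to 0.238 CPM, and such limits cover counting error only. In genes with 1 annotated transcript the unique and total reads were equal in all 21977 cases, so unique reads separate transcripts of 1 gene and say nothing of reads shared between genes. In genes with several transcripts 74.6% of reads were not unique, so the setting with unique reads drops most of their reads. Near-identical genes, such as members of the placental prolactin family, and overlapping genes are therefore uncertain. Antisense pairs are uncertain too.

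Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group, TMM normalization, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 12082 genes. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values are TMM-normalized and are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 11.8%.

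Before the data were examined, 31 gene lists were fixed with 637 distinct members, of which 599 were named in the tables and 483 were tested. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, which left 29 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, whereas fry tests a list against no change. A rule fixed at the same time picked the genes to name, not all of which appear in the text. It takes the CITED family, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 2, groups that did not overlap and no placeholder symbol. It adds up to 2 risen and 2 fallen members of each list by adjusted p, or the member with the smallest p where none passed, and the 6 members with the highest CPM of the prolactin and giant cell lists. Other members are named to show which genes stand behind a count, and these were chosen after their values were seen.

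The procedure was tested on simulated counts drawn from these libraries' means and depths, with 200 genes changed among 11931 tested. It recovered 57.8% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 1.92% of the calls were genes left as they were. Of simulated lists without a change, 1.5% fell under p = 0.05 by camera with the preset correlation. Those simulated genes varied independently of each other, which real genes do not. Their dispersion followed a trend with expression level, so no gene had a spread of its own. Only 200 genes were changed, against 2504 called in the real data, so these rates may not hold there.

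Replicates were compared before averaging: a chi-square of counts over genes was 8.2 to 29.7 per gene within groups, so no pair of libraries agreed within sampling noise. The alternatives were DESeq2 size factors, library size only, DESeq2 1.42.0, limma voom, no filter on low counts, a CPM of at least 1 in 3 libraries, unique reads, limma on log2(RPKM + 0.1) and log2(RPKM + 1), the replicate number as a block, and each library left out in turn. A removed length trend, voom with cyclic loess, and numbered copies of a symbol counted in the lists were added after the data had been seen. GC content was not checked, since no genome of this build was used here. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.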

Results

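Rcho-1 is a trophoblast stem line derived from a rat choriocarcinoma, and in differentiation medium its cells turn into trophoblast giant cells. Cells carrying a control shRNA or an shRNA against Cited2, a transcriptional coregulator that binds CBP and p300, were compared after 8 days of differentiation with 3 libraries per group. The comparison asks which transcripts differ when Cited2 is lowered during differentiation. Transcript reads numbered 12599613 to 18083789 per control library and 15123441 to 17926813 per Cited2 shRNA library. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No sequencing date or batch was given. Across genes, log2 CPM values correlated at 0.983 to 0.989 within groups and at 0.967 to 0.98 between groups, and the first principal component, with 53.5% of the variance, separated the groups.

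Cited2 itself (chromosome 1, 14515629 to 14518063, Rnor 5.0) was lower in the knockdown. It had 8889, 14072 and 14667 reads in control libraries 1 to 3 and 2103, 1909 and 2135 reads in Cited2 shRNA libraries 1 to 3. The level fell from 749 ± 63.1 CPM to 127 ± 4.86 CPM (SD, n = 3 each), which is 16.9% of control (log2 fold change -2.57, SE 0.09, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 5.6e-08). Its relative Cited1 stood at 8.68 ± 0.87 CPM in control and 5.66 ± 1.37 CPM in knockdown libraries (log2 fold change -0.62, edgeR adjusted p = 0.053), and did not pass the threshold. It passed with voom (adjusted p = 0.048), library size only (0.035), no filter on low counts (0.025), both RPKM settings (0.032 each) and without Cited2 shRNA library 2 (0.042). Cited4 had 0 reads in each library, which allows up to 0.166 to 0.238 CPM. Of the 2 tested members of the CITED family list, 1 fell over all genes and 2 fell adjusted over the list alone.

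Among single genes, Tpbpa, a marker of the spongiotrophoblast lineage, rose most, from 13.3 ± 1.66 to 174 ± 21.2 CPM, a 13.1-fold increase (chromosome 17, 6393064 to 6395434; log2 fold change 3.71, SE 0.12, edgeR adjusted p = 5.6e-08). The elastase gene Mmp12 rose 8.77-fold to 226 ± 32.1 CPM (chromosome 8, 5610392 to 5620293; log2 fold change 3.13, SE 0.21, edgeR adjusted p = 1.7e-05). The oxygen-regulated prolyl hydroxylase gene Egln3 rose 5.93-fold to 34.1 ± 6.62 CPM (chromosome 6, 84592894 to 84618360; log2 fold change 2.57, SE 0.23, edgeR adjusted p = 5.6e-05). Among genes with a mean log2 CPM of at least 2, the remaining largest rises were Nav3 at 5.72-fold, the prolactin family gene Prl8a5 at 5.43-fold, the thrombomodulin gene Thbd at 4.83-fold, the apolipoprotein gene Apoa4 at 4.7-fold and Lhfp at 4.52-fold. In the same range of expression Txnip, which encodes thioredoxin-interacting protein, fell most, from 45.8 ± 28.4 to 4.0 ± 0.88 CPM (chromosome 2, 218170012 to 218173900; log2 fold change -3.53, SE 0.47, edgeR adjusted p = 0.00053). Its control libraries were spread from 15.1 to 71.2 CPM. Besides Txnip and Cited2, the largest falls in that range were all genes of the mitotic spindle, kinetochore or chromosomes: Kif4a (log2 fold change -2.45), Top2a (-2.45), Kif2c (-2.30), Casc5 (-2.29), Kif23 (-2.28) and Nuf2 (-2.27).

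**Figure D1:**
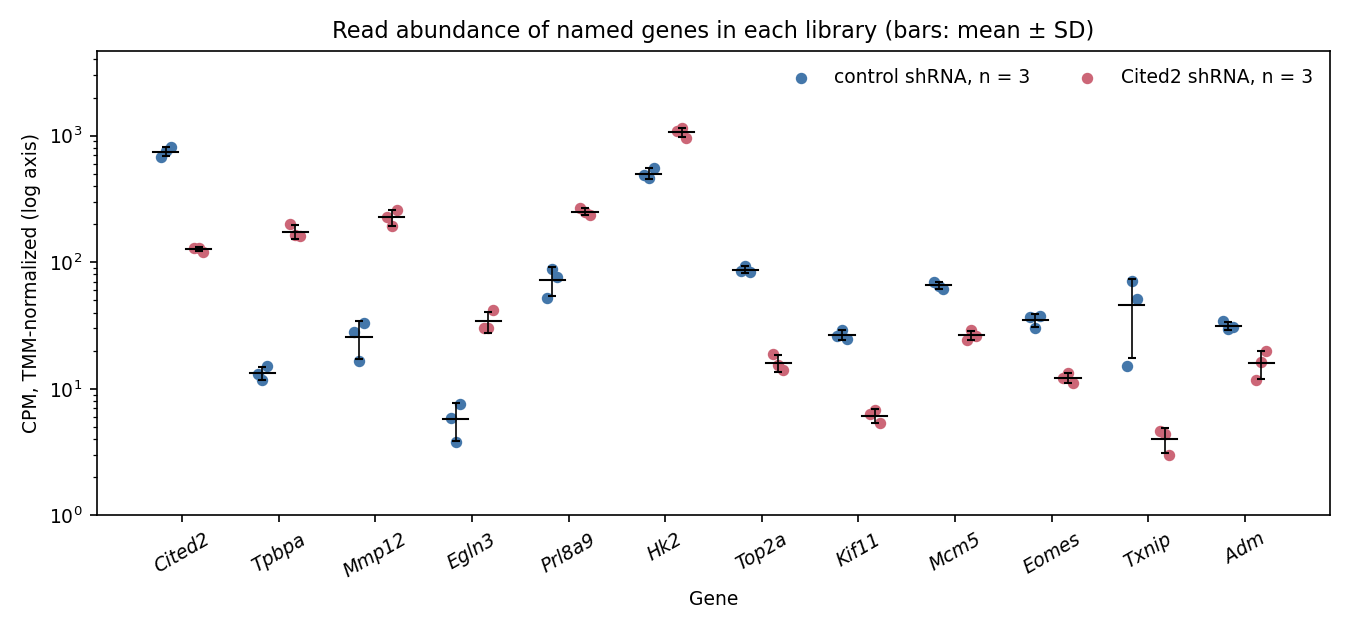
TMM-normalized CPM (log axis) of 12 genes in each library, with control shRNA in blue and Cited2 shRNA in red; horizontal bars are means and error bars the SD over 3 libraries. Cited2 lies at 749 CPM in control and 127 CPM in knockdown libraries, and the groups do not overlap for any of the 12 genes.

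Over the 12082 genes tested, edgeR called 2504 at an adjusted p under 0.05, of which 1304 rose and 1200 fell. Changes of at least 2-fold were found for 534 genes, 210 of them higher and 324 lower. With log2(RPKM + 1) they numbered 189, 51 higher and 138 lower, and with log2(RPKM + 0.1) 127 were higher. The groups did not overlap in CPM for 2455 of the called genes, and for 38.4% of all tested genes against 10% by chance. Scaling by library size only moved the split to 848 risen and 1857 fallen genes (31.3% risen against 52.1%), with a shift of the median log2 fold change of all genes to -0.11, against -0.01 in the main scaling. The count dropped to 1507 without control library 1, to 1238 without control library 3 and to 1468 without Cited2 shRNA library 2.

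**Figure D2:**
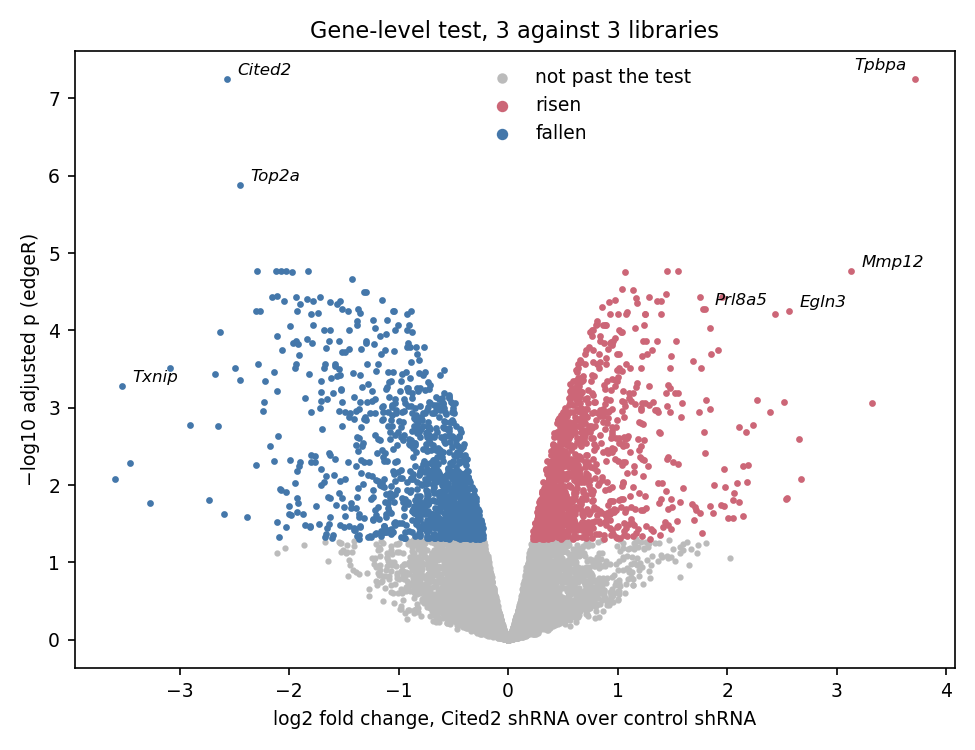
Log2 fold change (Cited2 shRNA over control shRNA) against the -log10 adjusted p of edgeR for the 12082 tested genes. The 1304 risen genes are in red, the 1200 fallen genes in blue and genes not past the test in grey.

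Most tested genes of the mitosis and DNA replication lists were lower in knockdown libraries. In the G2/M and mitosis list 29 of 32 tested members fell and 0 rose, and adjusted over the list alone 30 fell. Their median log2 fold change was -1.70 (camera adjusted p = 4.8e-57; adjusted p = 0.103 with an estimated correlation). Topoisomerase gene Top2a fell from 87.4 ± 5.26 to 16.0 ± 2.42 CPM (SE 0.12, edgeR adjusted p = 1.3e-06), and the spindle motor gene Kif11 fell from 26.7 ± 2.35 to 6.15 ± 0.75 CPM (log2 fold change -2.12, SE 0.15, edgeR adjusted p = 1.7e-05). Ube2c (-1.41), Cdk1 (-0.15) and Ccnf (0.10) did not pass. In the S phase and DNA replication list 30 of 38 tested members fell and 0 rose, with 34 fallen adjusted over the list alone and a median of -0.70 (camera adjusted p = 4.4e-28; adjusted p = 0.119 with an estimated correlation). Mcm5, a subunit of the replicative helicase, fell from 65.8 ± 4.24 to 26.4 ± 2.27 CPM (log2 fold change -1.31, SE 0.10, edgeR adjusted p = 3.2e-05), and the cyclin gene Ccna2 fell by 1.54 on the log2 scale. Among cell cycle inhibitors and cyclins D, 1 of 9 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.74). The risen gene was Cdkn1c (log2 fold change 0.46, edgeR adjusted p = 0.011), which turned to -0.12 with unique reads (adjusted p = 0.824). Those were only 976 to 2964 per library, against 21545 to 40278 total reads. Cdkn1c also missed the threshold with both RPKM settings, with cyclic loess and without control library 3. The call for Ccnd3, which fell (log2 fold change -0.72, edgeR adjusted p = 0.036), ended with DESeq2, with both RPKM settings and without control library 1 or 3 or Cited2 shRNA library 1 or 2. The inhibitor gene Cdkn1b fell from 33.5 ± 1.35 to 17.3 ± 3.39 CPM (edgeR adjusted p = 0.0011).

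**Figure D3:**
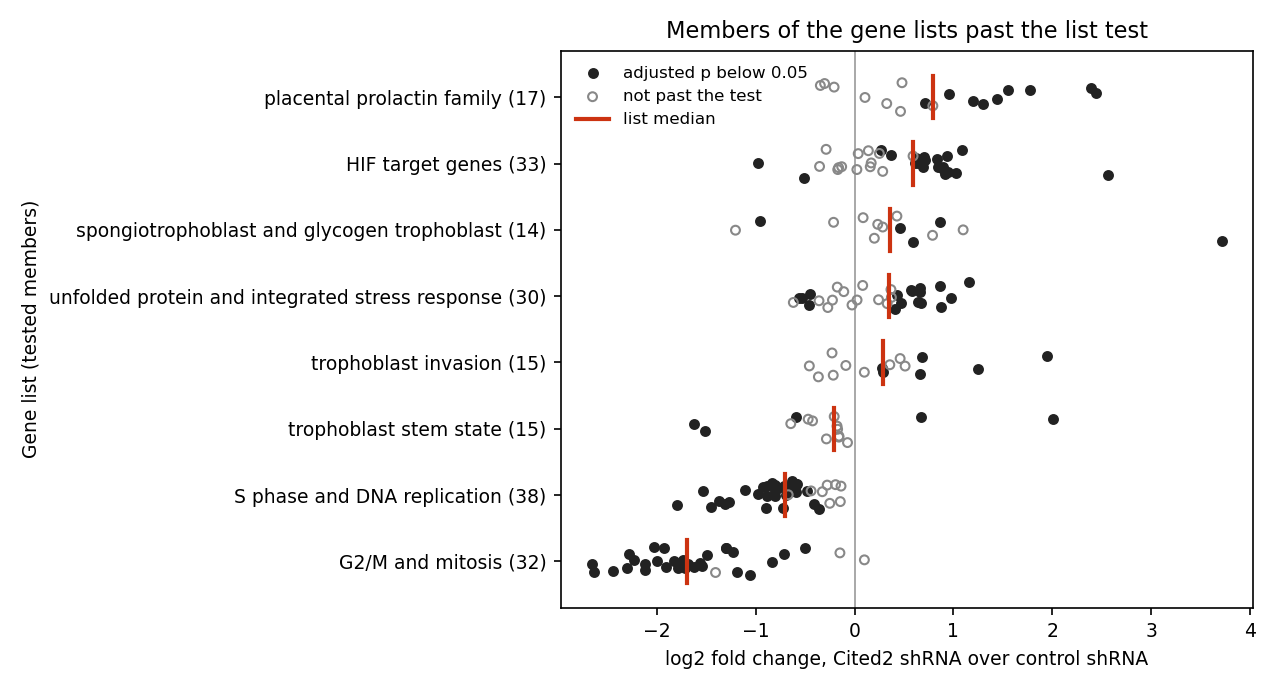
Log2 fold change of each tested member of the 8 gene lists past camera with the preset correlation, with the number of tested members in parentheses; filled points passed the edgeR threshold, open points did not, and red lines are list medians. Medians run from -1.70 for G2/M and mitosis to 0.79 for the placental prolactin family.

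Transcripts of genes that hypoxia-inducible factor (HIF) is known to induce were higher as a group, with exceptions. Of 33 tested HIF target genes 18 rose and 2 fell, and adjusted over the list alone 21 rose and 2 fell; the median log2 fold change was 0.59 (camera adjusted p = 3.1e-11; adjusted p = 0.205 with an estimated correlation). The median of HIF target genes was 0.39 without control library 2 and 0.37 with no filter on low counts. Besides Egln3, the hexokinase gene Hk2 rose from 502 ± 49.5 to 1065 ± 93.8 CPM (log2 fold change 1.09, SE 0.10, edgeR adjusted p = 5.7e-05). Fallen members were the peptide hormone gene Adm (log2 fold change -0.98, SE 0.17, edgeR adjusted p = 0.0024) and the growth factor gene Vegfa (-0.51, SE 0.12, edgeR adjusted p = 0.013). The call for Vegfa ended with an adjusted p of 0.054 without control library 3 and of 0.169 with unique reads. Vegfa has 4 annotated transcripts, and unique reads leave out those that its transcripts share. Of 8 HIF pathway components 1 rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.621). That gene was Hif1a (log2 fold change 0.41, edgeR adjusted p = 0.036), whose adjusted p was 0.136 without control library 1, 0.166 without control library 3, 0.113 without Cited2 shRNA library 1, 0.10 without Cited2 shRNA library 2, 0.08 with library size only, 0.089 with both RPKM settings and 0.09 with cyclic loess.

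The placental prolactin family, hormones made by trophoblast cells, was higher in part. Of 17 tested members 9 rose and 0 fell, with 10 risen adjusted over the list alone and a median of 0.79 (camera adjusted p = 5.2e-06; adjusted p = 0.273 with an estimated correlation). Without control library 1 or without control library 3, 5 members rose. Prl8a9 rose from 72.6 ± 18.9 to 250 ± 15.9 CPM (chromosome 17, 41098019 to 41103826; log2 fold change 1.78, SE 0.16, edgeR adjusted p = 5.4e-05), and Prl3d1, the placental lactogen I gene of giant cells, rose from 125 ± 36.5 to 367 ± 163 CPM (edgeR adjusted p = 0.0054). The most abundant members did not pass: Prl7a3 stood at 6814 ± 1221 and 9506 ± 2358 CPM and Prl2a1 at 7117 ± 286 and 7659 ± 957 CPM in control and knockdown libraries. Prl4a1, Prl3b1 and Prl7b1 did not pass either. Prl7a3 passed with no filter on low counts (log2 fold change 0.47, adjusted p = 0.0014), without control library 2 (0.62) and without Cited2 shRNA library 3 (0.66), against 0.48 in the main test. Leaving out Cited2 shRNA library 3 also let Prl3b1 pass at 0.63, against 0.33. Reads of close copies such as Prl3d1 and Prl3d2, or the Prl8a genes, could be split between them, so their single values are uncertain.

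The other trophoblast lists past camera with the preset correlation moved up, apart from the stem state list. In the spongiotrophoblast and glycogen list 4 of 14 rose and 1 fell, with 6 risen and 1 fallen adjusted over the list alone (median 0.36, camera adjusted p = 2.1e-05; adjusted p = 0.119 with an estimated correlation). The median of this spongiotrophoblast list was 0.13 with log2(RPKM + 1). Next to Tpbpa, the glycogen branching enzyme gene Gbe1 rose 1.82-fold (edgeR adjusted p = 0.001). The member that fell was Gjb3 (log2 fold change -0.95, edgeR adjusted p = 0.025). Its call ended with cyclic loess and without control library 1 or 3 or Cited2 shRNA library 1 or 2. In the invasion list 6 of 15 rose and 0 fell, with the same counts adjusted over the list alone (median 0.29, camera adjusted p = 8.1e-04; adjusted p = 0.119 with an estimated correlation). The median of this invasion list was 0.17 with log2(RPKM + 1), and 4 to 7 members rose when 1 library was left out. Its leading genes were the metalloproteinase inhibitor gene Timp3, at 3.86-fold, and the urokinase gene Plau, at 2.38-fold; Timp3 lies within the span of Syn3, so its reads are uncertain. The stem state list had 2 risen and 3 fallen members of 15, and the same adjusted over the list alone (median -0.21, camera adjusted p = 0.030; adjusted p = 0.273 with an estimated correlation). Its camera call ended with voom (adjusted p = 0.06), with both RPKM settings (adjusted p = 0.158 and 0.115) and without Cited2 shRNA library 3 (adjusted p = 0.072). The stem cell transcription factor gene Eomes fell from 34.8 ± 4.12 to 12.2 ± 1.12 CPM (edgeR adjusted p = 5.4e-05) and Satb1 from 113 ± 30.4 to 36.4 ± 1.26 CPM (edgeR adjusted p = 1.0e-04), while Phlda1 rose 1.59-fold.

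The giant cell list had 6 risen and 4 fallen members of 20, or 8 and 5 adjusted over the list alone, and did not pass camera (adjusted p = 0.604). Serpinb9d rose 1.74-fold and the receptor gene Flt1 2.05-fold, while Adm fell; Flt1 overlaps Pan3, so its reads are uncertain. Tfpi, the most abundant giant cell member, stood at 8457 ± 1070 CPM in control and 13331 ± 2239 CPM in knockdown libraries (log2 fold change 0.66, edgeR adjusted p = 0.0061). Its call ended with both RPKM settings (adjusted p = 0.067 and 0.091). Also among the 6 most abundant giant cell members, Cyp11a1 rose (log2 fold change 0.66, edgeR adjusted p = 0.016) and Gata3 fell (-0.57, edgeR adjusted p = 0.018). Both calls ended without control library 1 or 3, and that for Cyp11a1 also without Cited2 shRNA library 2. Hand1, Gata2 and Lifr did not pass. Hand1 passed without Cited2 shRNA library 3 (log2 fold change -0.57, adjusted p = 0.015), and Lifr with library size only (adjusted p = 0.021) and both RPKM settings (adjusted p = 0.03 and 0.029). The labyrinth list had 0 risen and 1 fallen of 12 (camera adjusted p = 0.74), and imprinted placental genes had 3 risen and 1 fallen of 12 (camera adjusted p = 0.784). For both, the counts were the same adjusted over the list alone. The median of the imprinted list, 0.08, was above 0 and its mean, -0.07, below. Mest, an imprinted gene, fell from 66.0 ± 5.39 to 24.6 ± 1.97 CPM (edgeR adjusted p = 2.2e-05).

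Genes of the unfolded protein and integrated stress response were higher in part, with 13 risen and 4 fallen of 30, or 16 and 5 adjusted over the list alone (median 0.35, camera adjusted p = 5.2e-04; adjusted p = 0.239 with an estimated correlation). The median of this unfolded protein response list was 0.17 with log2(RPKM + 1). The risen members included endoplasmic reticulum chaperone genes, with Dnajb9 at 2.23-fold (edgeR adjusted p = 9.3e-05) and Manf at 1.84-fold (edgeR adjusted p = 1.5e-04). Those that fell were Shmt2, Psat1, Trib3 and Atf3, of which Shmt2 and Psat1 encode enzymes of one-carbon and serine metabolism. Fallen members numbered 2 without control library 3 and 2 without Cited2 shRNA library 2. Heat shock genes had 1 risen of 14 (camera adjusted p = 0.646), interferon response genes 1 risen and 2 fallen of 19 (0.255), NF-kB and cytokine genes 2 risen and 1 fallen of 9 (0.574), and p53 target genes 5 risen and 2 fallen of 22 (0.604). Adjusted over the list alone these became 1 and 0, 1 and 5, 2 and 1, and 6 and 3. The interferon regulator gene Irf1 fell by 0.99 on the log2 scale (edgeR adjusted p = 6.0e-04), and Usp18, which restrains interferon signalling, rose 2.74-fold.

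In the list of TGF-beta and SMAD targets 4 of 16 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.574, direction up, with a median of -0.03 and a mean of -0.02). Smad7, an inhibitor of SMAD signalling, rose 1.55-fold (edgeR adjusted p = 8.7e-04) and the plasminogen activator inhibitor gene Serpine1 1.58-fold (edgeR adjusted p = 2.4e-04). Angiogenic factors had 1 risen and 3 fallen of 8 (camera adjusted p = 0.574), and immediate early genes had 2 risen and 4 fallen of 17 (0.646), with Fos lower by 1.11 on the log2 scale and Klf4 1.7-fold higher. Cholesterol synthesis genes had 8 risen and 2 fallen of 25 (camera adjusted p = 0.176). Steroidogenesis genes had 3 risen and 1 fallen of 12 (camera adjusted p = 0.574). Star, which carries cholesterol into mitochondria, was 2.13-fold higher, while Cyp17a1 fell by 0.42 on the log2 scale (edgeR adjusted p = 0.026). The call for Cyp17a1 ended without control library 2 or 3 or Cited2 shRNA library 2. Extracellular matrix genes had 2 risen and 5 fallen of 19 (camera adjusted p = 0.627). The fibronectin gene Fn1 rose from 3260 ± 504 to 7840 ± 1317 CPM (edgeR adjusted p = 2.0e-04). A gene of placeholder symbol overlaps its span, so its reads are uncertain. Among the fallen members, Sdc4 was lower by 0.88 and Sdc1 by 0.44 on the log2 scale (edgeR adjusted p = 0.002 and 0.005). Adjusted over the list alone, the risen and fallen counts of these lists were 1 and 3, 3 and 5, 10 and 3, 3 and 2, and 3 and 6, in the same order. Oxidative phosphorylation genes had 0 risen and 4 fallen of 26 (camera adjusted p = 0.059), or 0 and 7 adjusted over the list alone. This list passed in 10 alternatives, among them camera with library size only (adjusted p = 0.00957) and with voom (adjusted p = 0.0117). The 10 include fry (adjusted p = 0.0112), which tests a list against no change and not against other genes. Cytosolic ribosomal protein genes had 2 risen and 1 fallen of 28 (0.604) and lysosome genes 0 risen and 3 fallen of 19 (0.551), both unaltered adjusted over the list alone. The lysosome list passed camera with voom and cyclic loess (median -0.13, adjusted p = 0.0198). Against no change, cholesterol synthesis and steroidogenesis passed by fry (adjusted p = 0.0285 and 0.0166), though camera told neither apart from other genes. The steroidogenesis list had 6 members above 0 and 6 below.

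Of 7 fibroblast and stromal markers 2 rose, Pdgfra and Pdgfrb (camera adjusted p = 0.49). Both calls ended with library size only (adjusted p = 0.083 and 0.066), with both RPKM settings and without control library 1 or 3 or Cited2 shRNA library 1 or 2. That for Pdgfrb also ended without control library 2 (adjusted p = 0.081). Of 5 endothelial markers 2 fell (camera adjusted p = 0.574), Cdh5 by 0.35 and Pecam1 by 1.58 on the log2 scale. Of 3 yolk sac markers Apoa4 rose (camera adjusted p = 0.176), and the log2 fold changes of all 3 were above 0. The yolk sac list passed camera without Cited2 shRNA library 3 (median 0.96, adjusted p = 0.0116). It also passed by fry (adjusted p = 0.0432), which tests against no change. Among leukocyte markers 2 were tested and 0 passed edgeR, and the member with the smallest p was Cd68, at 2.57 ± 0.67 and 3.0 ± 0.29 CPM. For all 4 lists the counts were the same adjusted over the list alone.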

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

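The length correction, cyclic loess and the lists with numbered copies were chosen after the data had been seen. The log2 fold change of Cited2 lay between -2.67 and -2.52 in all 18 alternatives of the gene test. The number of called genes ranged from 1238 without control library 3 to 3083 without Cited2 shRNA library 3, with 621 to 1572 risen and 617 to 1511 fallen over the 6 left-out libraries. It was 1507 without control library 1 and 1468 without Cited2 shRNA library 2. Fewer libraries widen the errors, but the count also grew when Cited2 shRNA library 3 was left out, and the cause was not tested. This library differed most within its group. The chi-square per gene was 29.7 against Cited2 shRNA library 1 and 13.9 against library 2, but 8.5 between libraries 1 and 2. With library size only, 848 genes rose and 1857 fell. RPKM values gave 747 risen genes with a pseudocount of 0.1, 127 of them at least 2-fold, and 749 with a pseudocount of 1. With the latter 189 genes changed at least 2-fold, 51 up and 138 down. A larger pseudocount shrinks the folds of low genes, which does not account for the uneven split. RPKM values carry no TMM scaling. Of their calls 30.2% rose with a pseudocount of 0.1 and 29.9% with 1, near the 31.3% with library size only. Of the genes called in the main test, 2048 were also called with library size only, 2388 by DESeq2 and 2404 by voom, each in the same direction.

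The replicate numbers did not pair the libraries: deviations from the group means correlated at -0.14, 0.03 and 0.16 for numbers 1 to 3, while control 2 and Cited2 shRNA 1, which carry different numbers, reached 0.321. With the replicate block 2309 genes were called, 2196 of them also called without it, and the number of lists past camera stayed at 8.

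The median of the stem state list kept its sign in every alternative but missed the threshold of camera with voom (-0.21), with RPKM (-0.28 and -0.26 for the pseudocounts 0.1 and 1) and without Cited2 shRNA library 3 (-0.24). Without 1 library it lay between -0.32 and -0.13, and 3 to 6 members fell, the 6 without control library 2. The cause was not tested. With the correlation estimated per list 0 lists passed, against 8 with the preset value and 12 by fry. The adjusted p was then 0.103 for G2/M and mitosis, 0.119 for S phase, for spongiotrophoblast and for invasion, 0.205 for HIF targets, 0.239 for the unfolded protein response and 0.273 for the prolactin family and the stem state. Without 1 library 5 to 11 prolactin members rose, 5 of them without control library 1 or 3. Fallen members of the unfolded protein response numbered 2 to 4, with 2 without control library 3 or Cited2 shRNA library 2. With both RPKM settings 2 spongiotrophoblast members rose. With log2(RPKM + 1) the median of this list was 0.13 against 0.36, that of the unfolded protein response 0.17 against 0.35, of invasion 0.17 against 0.29 and of the prolactin family 0.50 against 0.79. The HIF target median was 0.39 without control library 2 and 0.37 with no filter, against 0.59.

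The first principal component held 37.5% of the variance with no filter on low counts, 58.2% with a CPM of at least 1, 63.1% with log2(RPKM + 1), and 52.7 to 60.8% without 1 library. Of 88 genes picked by the naming rule and past the threshold, 27 missed it without at least 1 library and 0 turned sign there. Not all of these genes are named in the text. Cdkn1c turned to -0.12 with unique reads (adjusted p = 0.824), and the cause was not tested. That setting kept 976 to 2964 reads of this gene per library, against 21545 to 40278 total reads. Total reads with introns were not run, as the tables used here hold no such column, and DESeq2 gave no list test. With 3 simulated libraries per group at these depths, 57.8% of 1.5-fold and 98.5% of 4-fold changes were recovered.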

Other observations

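Every test of an explanation given here, apart from the counts of other splits of the libraries, was chosen after the result it bears on had been seen, as were the symbol families and the single genes named here. Grouping genes by the letters of their symbols gave 182 families with at least 8 tested members, of which 7 passed camera with the preset correlation and 0 with an estimated one. Of these, 8 of 10 Mcm genes fell and 0 rose (median -0.90, camera adjusted p = 2.2e-13; adjusted p = 0.918 with an estimated correlation), and the Prl family overlaps the prolactin list. Further, 14 of 32 kinesin (Kif) genes fell and 3 rose (median log2 fold change -0.48, camera adjusted p = 6.6e-09; adjusted p = 0.96 with an estimated correlation). Of 8 chromobox (Cbx) genes, which encode chromatin-binding proteins, 5 fell and 0 rose (median -0.43, camera adjusted p = 0.025). Of 9 annexin (Anxa) genes 5 rose and 1 fell (median 0.42, camera adjusted p = 0.025), and of 29 sorting nexin (Snx) genes 9 rose and 0 fell (median 0.19, camera adjusted p = 0.046). Of 9 Dnajb co-chaperone genes 4 rose and 0 fell (camera adjusted p = 0.046). With an estimated correlation the adjusted p of the chromobox, annexin, sorting nexin and Dnajb families was also 0.96. Arrdc4, an arrestin family gene like Txnip, also fell (log2 fold change -1.80).

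Shares of transcripts within a gene were tested from unique reads, which the gene test does not use. In 356 genes with at least 2 transcripts that passed the filter, diffSpliceDGE of edgeR called 0 genes, with 43 at an unadjusted p under 0.05 and a smallest adjusted p of 0.304. In simulated libraries the test recovered 100% of genes whose leading transcripts were fully swapped and differed at least 2-fold. Of its simulated calls 7.28% were genes not swapped. Smaller shifts were not simulated, so the power to find them is unknown.

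Lower cell division transcripts were weighed first. The G2/M list had a median of at most -1.70 over 3 scalings and of at most -1.64 once a trend with length or with expression level was removed, which argues against either as the whole cause. A smaller share of stem cells would lower the stem state list about as much if only stem cells made its members. Its median lay 1.49 above that of the G2/M list, against an SD of its members of 0.84. Of its 15 tested members 13 lay below 0, with Eomes at -1.51 and Satb1 at -1.62, while Phlda1 (0.67) and Zic3 (2.01) rose. Zic3 lay near the floor, with 2 to 6 reads per control library and 13 to 22 per Cited2 shRNA library. Its call ended without control library 2 or 3 or Cited2 shRNA library 1 or 2, and with log2(RPKM + 1). Members also made by other cells would fall less, and the SD is not an error of the median, so the gap cannot decide this. An off-target effect of the shRNA or a difference in cell density could give the same transcripts and was not tested.

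Higher HIF target transcripts kept a median of at least 0.49 over 3 scalings and of at least 0.49 with either trend removed, though it was 0.39 without control library 2 and 0.37 with no filter on low counts. A rise of glycolysis genes alone was tested on the 19 members outside glycolysis. Their median of 0.29 fell just short of a first bound of 0.3 and decided nothing, and a count was then chosen in its place: 10 of the 19 rose (52.6%, against 10.8% of all tested genes; one-sided exact hypergeometric test, p = 7.7e-06, which treats genes as independent), while Adm and Vegfa fell. That count, picked after the first test had missed its bound, argues against glycolysis genes alone with less weight than a test fixed beforehand. CITED2 is known to compete with HIF for CBP and p300, and the median of 0.59 would suit its loss. This cannot be told apart from lower oxygen at the cells or a change in density, which could raise the same genes.

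Higher transcripts of neighbouring placental and protease genes were weighed last. If a gain of a whole block as DNA were the whole cause and acted equally on its genes, they would share 1 fold change. The heterogeneity of log2 fold changes per degree of freedom was 16.2 in the prolactin block (chromosome 17, 40184558 to 44793065, 27 genes tested, 10 risen and 1 fallen), 64.0 in the Tpbpa and cathepsin block (chromosome 17, 5492909 to 6453399, 4 of 9 risen) and 43.5 in the metalloproteinase block (chromosome 8, 5610392 to 6058253, 4 of 7 risen). The Tpbpa and metalloproteinase blocks were drawn around genes already seen to rise strongly, which favours high values there. These values argue against 1 fold change shared by all tested genes of a block. They cannot decide on a gain to which genes respond unequally, nor on regulation shared by neighbours, which was not tested. Reads shared between near-identical copies cannot be told apart from changes of single copies, as 0 single-transcript genes had unique reads below their total and the unique column thus does not bear on sharing between genes.

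The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2504 genes and the highest of the other splits 0 (edgeR; at most 1543 at an unadjusted p under 0.05, against 4161), so 1 of the 10 splits gave as many. For changes of at least 2-fold the real count was 534 and the highest other 0, again 1 of 10. For lists past camera with the preset correlation the real count was 8 and the highest other 9, and 3 of the 10 splits gave at least 8. The splits thus lend the number of lists past that test no support. By fry 12 lists passed in the real split and at most 0 in the others. Each other split mixes control and Cited2 shRNA libraries unevenly. Part of a difference between these groups therefore stays between its sides, while the rest widens its spread and lowers its counts. The 0 by fry thus lends no support to single lists. For G2/M and mitosis the camera adjusted p was 4.8e-57 in the real split and at least 1.7e-12 in the others; for the prolactin family it was 5.2e-06, and 4 of the 10 splits, the real one included, gave a value as small, down to 3.4e-08. For the stem state it was 0.0302 in the real split and 0.0117 in another, so 2 of 10 gave a value as small. By camera the splits thus lend neither list support. By fry each passed in the real split only (adjusted p = 0.0439 and 0.0282), which given that mixing adds none. The smallest camera adjusted p of another split was 1.9e-14 for S phase and 6.4e-06 for HIF targets. It was 0.0049 for the unfolded protein response, 0.0143 for spongiotrophoblast and 0.0381 for invasion. These lists had their smallest value in the real split, but all 8 lists passed camera in a mixed split too. A mixed split keeps part of a group difference, so it cannot show which lists would pass without such a difference. The splits therefore cannot decide whether passing camera at 0.05 sets a list apart.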
